A study of Homo sapiens with 2 samples.

How the data were processed

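The scanner files of both arrays were used. The intensity values in them had been background-subtracted by spatial detrending and multiplicatively detrended before they were deposited, per the file headers, with Agilent Feature Extraction 10.7.1.1 and protocol GE1_107_Sep09; the submitters' processing notes name version 9.5.1.1. Per the labels' protocols, RNA was extracted with TRIzol and the SV Total RNA Isolation kit and labelled with Cy3 by Low Input Quick Amp labelling. Probe positions are on GRCh37 as given in the files; the GRCh38.p14 gene table served for current names and gene lengths only, with 31038 of 31770 probes that carry an NM or NR accession matched. Exon annotation of the probes was not used.

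Spots flagged as outliers were dropped (44 on the DMSO array, 54 on the CX-4945 array; 0 were saturated), and spots of the same probe were averaged. A probe counted as well above background when at least 0.5 of its spots had that flag. Each array was divided by its 75th percentile over all non-control probes (296.8 for DMSO, 187.4 for CX-4945). A gene was read from its brightest probe among those well above background on both arrays, and the log2 difference was CX-4945 minus DMSO. A gene with no such probe but one above background on a single array was given a bound. Each gene list was compared by its median with 10000 random lists drawn from 20 bins of mean signal. No test between the conditions was possible.

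The lists, the rule for named genes and the alternatives were fixed before the data were examined, except the protein-coding background of the random lists. NR5A1, NR0B1, MC2R, 9 genes of steroid synthesis, the 4 CLK genes and the 3 casein kinase 2 genes were named whatever their value. To these were added the 14 protein-coding and 3 non-coding genes with the largest difference each way, among those above the 25th percentile of signal whose probes all moved the same way, up to 3 examples each way from each list that differed at least 1.5-fold, and the 4 genes with the largest bound each way.

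Alternatives were normexp background correction, quantile normalization, median centring, loess, centring on the E1A spike-ins, a percentile over probes above background on both arrays, the series value table, outlier spots kept, no filter and a stricter filter on dim probes, a mean over the gene's probes and thresholds of 1.5-fold and 3-fold. The values in the series table were linear, with no gene centring; the sorted columns of both arrays were identical (median 12.7 each) and kept the scanner's order (Spearman's rho over probes 0.999999 and 0.999996), as quantile normalization gives.

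In a simulated pair of arrays with 200 changed genes, 3-fold, 5-fold and 10-fold differences were called in 100% of cases and 1.5-fold differences in 0%. Past 2-fold lay 28 of 18827 unchanged genes. Changed genes were drawn well above the detection floor, and the scatter of unchanged genes was set beforehand, without culture or labelling differences. These rates therefore check the code and do not estimate errors on the real arrays. A raised list of 30 genes stood at percentile 100 and an unchanged one at 13.45, and 50 of 50 genes with 1 moved probe were found. Separately, for sets of independent normal values not drawn from the arrays, bootstrap intervals covered the true value in 94.8% of 400 runs. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.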

Results

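Gene expression was profiled in H295R cells, an established human adrenocortical carcinoma line that makes mineralocorticoids, glucocorticoids and adrenal androgens. Cells had been kept for 24 h with 5 μM CX-4945 or with its solvent, dimethyl sulfoxide (DMSO). CX-4945 (silmitasertib) is a small-molecule inhibitor of casein kinase 2, and it is also known to inhibit the CDC2-like kinases (CLKs), which phosphorylate the serine/arginine-rich (SR) splicing factors. Each condition was measured on 1 single-colour (Cy3) Agilent array, and both arrays lay on the same slide. With 1 array per condition there was no replicate, so no test was possible and every value below describes these 2 libraries. Each array held 60901 non-control spots for 58201 probes. On the DMSO array 26728 probes (45.9%) were well above background, on the CX-4945 array 25791 (44.3%), and on both arrays 24145, which gave a value for 18634 genes. The log2 difference between the arrays had an SD of 0.073 over repeated spots of the same probe (279 probes, 2709 spots). That spread covers spotting and scanning only, not differences between cultures or labelling reactions. All changes are log2 values of CX-4945 minus DMSO after each array was set to its 75th percentile, and "2-fold" means a log2 difference of at least 1 in size.

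With CX-4945, 2599 genes (13.9%) were at least 2-fold higher and 2617 (14.04%) at least 2-fold lower, while 13418 changed by less. Beyond 10-fold lay 145 genes that were higher and 112 that were lower. Among 12646 protein-coding genes, 1687 were 2-fold higher and 2003 lower; among 1510 named non-coding RNAs the counts were 257 and 240. The balance between the directions depended on the scaling. Higher genes made up 49.8% of the 2-fold differences after 75th percentile scaling, 33.9% after median centring (1777 higher, 3465 lower), 38.3% after loess (1987 and 3202) and 9.504% when the arrays were centred on the E1A spike-in controls (721 and 6865). Median centring moved the median of all genes by −0.24, loess by −0.18 and the spike-ins by −0.87. A value given below therefore reads 0.87 lower relative to the spike-ins, and some that lie inside 2-fold here are past 2-fold lower there. No scaling or background correction tried moved the median of all genes up. A list median below 0 thus had little room to turn positive, so a negative sign under every scaling is a weak check. Of the 2-fold differences, 714 higher and 1982 lower genes were called under every scaling and background correction tried. Of 176 genes past 2-fold that the naming rule covers, 37 were below it relative to the spike-ins and 17 under normexp background correction. As a mean over the probes of the gene 10 were below it, and 0 changed sign where measured. Under median and spike-in centring no change of sign was possible at that size.

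The series asked whether a compound that alters splicing of NR5A1 impairs steroid synthesis, and the transcripts of several steroid-forming enzymes were much lower with CX-4945. SULT2A1, the sulfotransferase that forms dehydroepiandrosterone sulfate, was 44.2-fold lower (log2 −5.47). CYP11A1, which makes pregnenolone from cholesterol in the first enzymatic step of the pathway, was 9.17-fold lower (−3.20). HSD3B1 was lower by 6.95-fold (−2.80), HSD3B2 by 5.26-fold (−2.40) and CYP17A1, the 17-hydroxylase on the way to cortisol and androgens, by 4.84-fold (−2.28). Some genes of the pathway were higher. CYP19A1, the aromatase that makes oestrogens, was 5.92-fold higher (2.57; its second measured probe gave 1.34), and HSD17B1 was 3.34-fold higher (1.74) and HSD17B3 2.73-fold (1.45), both below 2-fold relative to the spike-ins and HSD17B3 also under normexp. AKR1C3 was 4.65-fold lower (−2.22), read by a probe in a family of close paralogs. STAR, which carries cholesterol into mitochondria, differed by −0.43, CYP21A2 by 0.93 and the corticotropin receptor MC2R by −0.59. Relative to the spike-ins STAR (−1.30) and MC2R (−1.46) were past 2-fold lower. The aldosterone synthase CYP11B2 differed by 0.68, and by −0.19 relative to the spike-ins. CYP11B1 was not well above background on either array. The genes HSD3B1 and HSD3B2, CYP11B1 and CYP11B2, and CYP21A2 with its pseudogene are near-identical in sequence, so their probes can read more than 1 gene and these values are uncertain.

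Of 24 measured members of the steroidogenesis list, 9 were at least 2-fold lower and 4 higher, or 15 and 1 relative to the spike-ins. Their median was −0.46, or −0.64 relative to the median of all genes, at percentile 0.24 among 10000 random lists matched on signal. It was negative under every scaling, from −1.33 relative to the spike-ins to −0.46, the main value, which was the highest of them. NR5A1 itself, which encodes steroidogenic factor 1, a nuclear receptor that drives many of these genes, differed by −0.21. Relative to the spike-ins NR5A1 was past 2-fold lower (−1.08). Its probe covers chromosome 9, 127244219 to 127244278 on the minus strand (GRCh37), near the 3' end of the transcript (position 2331), with the sequence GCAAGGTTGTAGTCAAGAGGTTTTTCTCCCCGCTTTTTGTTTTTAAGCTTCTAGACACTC. A single probe there reads neither exon skipping nor circular RNA of NR5A1, so neither was measured by these arrays. The probes of SULT2A1 (chromosome 19, 48377923 to 48377982), CYP11A1 (chromosome 15, 74631018 to 74631077) and STAR (chromosome 8, 38001178 to 38001237) each lie within 1 uninterrupted stretch of the genome.

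**Figure D1:**
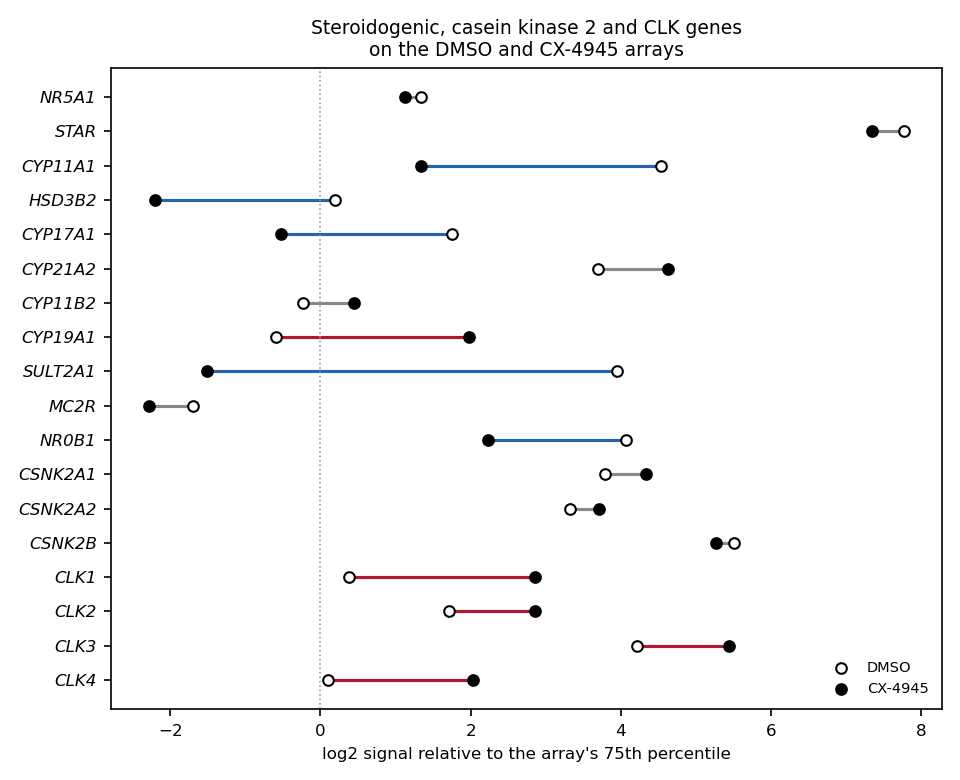
Log2 signal relative to each array's 75th percentile (x axis) of the measured genes that were to be named whatever their value, on the DMSO (open points) and CX-4945 array (filled points), joined by blue lines where at least 2-fold lower, red where at least 2-fold higher and grey otherwise. SULT2A1 (−5.47) and CYP11A1 (−3.20) show the longest lines to the left, and CYP19A1 (2.57) and CLK1 (2.48) the longest to the right.

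Of 26 measured cholesterol synthesis and uptake genes, 22 lay below the median of all genes, 10 were at least 2-fold lower and 3 higher, with a list median of −0.56 (percentile 0.05 of the random lists) that was negative under every scaling. The lowest were FDFT1, which encodes squalene synthase (−1.65), TMEM97 (−1.62) and MSMO1, a sterol demethylation enzyme (−1.47). The 3 higher members were NPC1L1, the intestinal cholesterol uptake protein (5.67), TM7SF2 (1.82) and SC5D (1.48); relative to the spike-ins, TM7SF2 and SC5D were no longer 2-fold higher.

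Among transcriptional regulators of the adrenal cortex, 5 of 19 measured members were 2-fold higher and 2 lower, with a median of 0.16 at percentile 47.3, which was −0.08 after median centring and −0.71 relative to the spike-ins. NR4A2, an orphan nuclear receptor induced by trophic hormones, was 46.98-fold higher (5.55), CITED2 9.13-fold (3.19) and the oxysterol receptor gene NR1H2 2.99-fold (1.580; below 2-fold relative to the spike-ins). NR0B1, which encodes DAX-1, a repressor of steroidogenic factor 1, was 3.60-fold lower (−1.85), although a second, dimmer probe of it gave −0.24. NR2F1 was 3.49-fold lower (−1.80) and GATA4 differed by −0.82, while other probes of GATA4, of similar signal, gave −0.125 and −0.502. NR2F1 was below 2-fold under normexp background correction. ESR1 was well above background on the DMSO array only, at least 3.36-fold higher there.

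Transcripts of the kinases that CX-4945 is known to inhibit were measured as well. Differences of the casein kinase 2 subunits were 0.55 for CSNK2A1, 0.39 for CSNK2A2 and −0.24 for CSNK2B. Second probes gave 0.86, 0.99 and −0.37 in that order. The list median was 0.39 (percentile 68.5), or −0.49 relative to the spike-ins, where CSNK2B was past 2-fold lower (−1.11). All 4 CLK genes were at least 2-fold higher: CLK1 by 5.58-fold (2.48), CLK4 by 3.82-fold (1.93), CLK3 by 2.33-fold (1.22) and CLK2 by 2.23-fold (1.16). CLK2 was below 2-fold under normexp, and CLK2 and CLK3 under median centring and relative to the spike-ins, where CLK1 stayed at 1.61 and CLK4 at 1.06. The 2 measured probes of CLK1 gave 2.48 (chromosome 2, 201718707 to 201719388, joining separate genomic pieces) and 2.57 (201725962 to 201726021). SRSF6, an SR protein gene, was 4.22-fold higher (2.08), and TRA2A differed by −0.72. Over the CLK, DYRK and SR protein list, 8 of 24 measured members were 2-fold higher and 0 lower, or 3 and 6 relative to the spike-ins. The list median was 0.39 at percentile 88.9 and turned to −0.48 relative to the spike-ins. SRSF12 was well above background on the DMSO array only, at least 2.74-fold higher there. Of 51 hnRNP and core spliceosome genes, 8 were 2-fold higher and 3 lower, or 0 and 12 relative to the spike-ins. Their median was 0.55 at percentile 99.9, and −0.32 relative to the spike-ins. PRPF3 (1.81), HNRNPA0 (1.51) and SNRNP70 (1.46) were the highest, all 3 below 2-fold relative to the spike-ins. The lowest were HNRNPA3 (−1.53), HNRNPDL (−1.04) and HNRNPD (−1.03), all 3 below 2-fold as a mean over their probes; a second probe of HNRNPDL gave 0.91, and the 5 measured probes of HNRNPA3 ranged up to 1.60. Genes known to regulate circular RNAs stood at a median of 0.11 (percentile 38.1; −0.76 relative to the spike-ins, and below 0 under normexp, median centring and loess), with 2 of 15 lower, including MBNL3 (−1.68), and 0 higher.

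**Figure D2:**
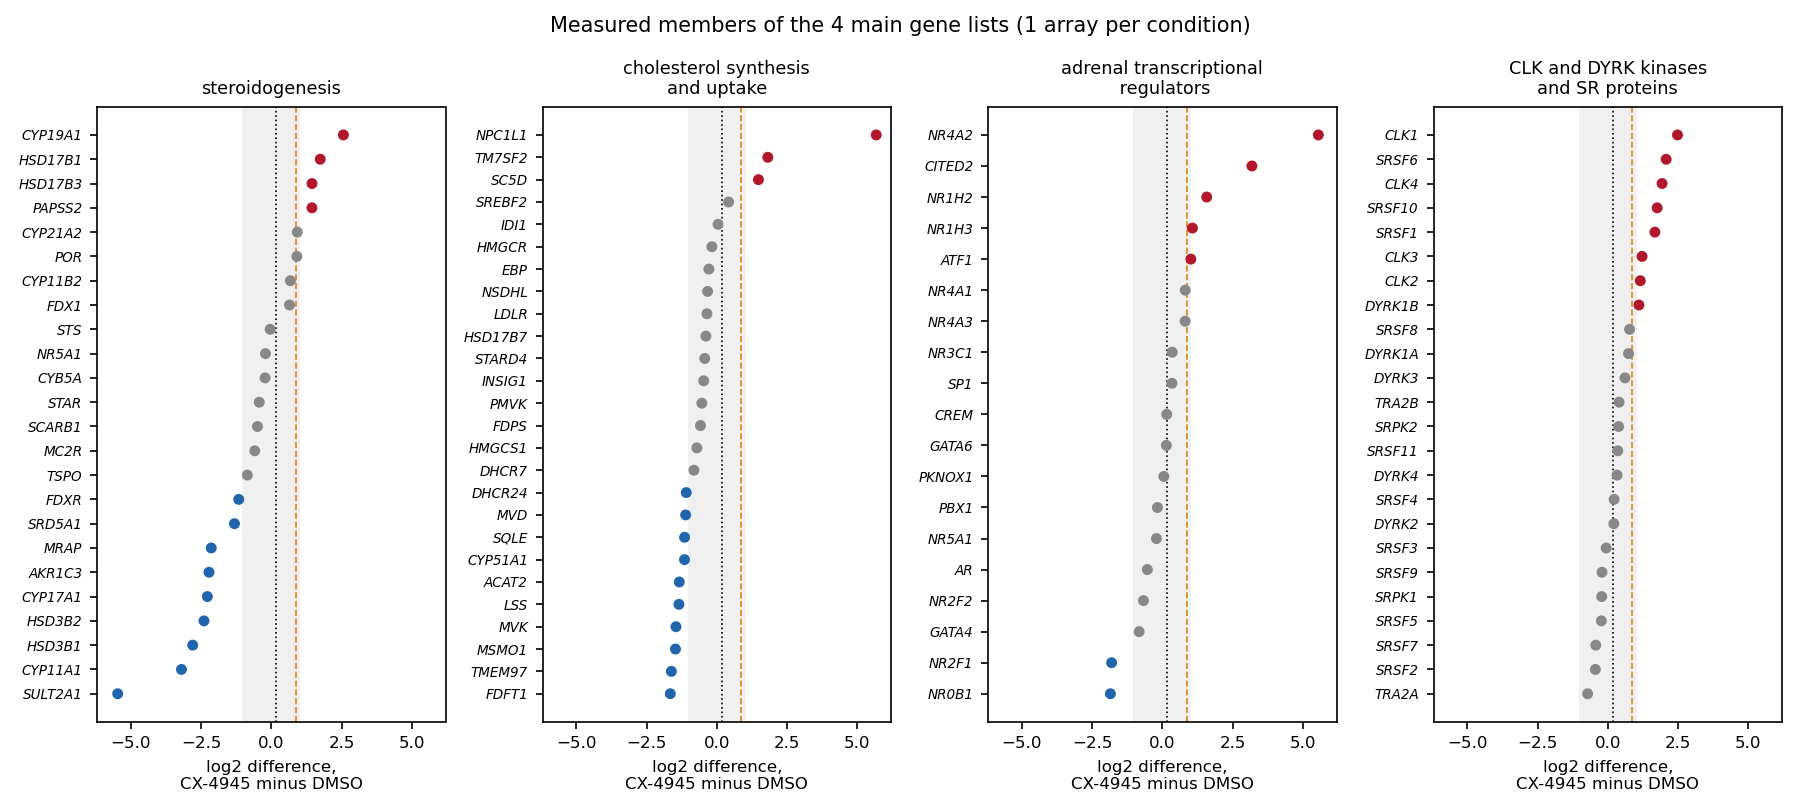
Log2 difference, CX-4945 minus DMSO (x axis), of each measured member of the 4 main gene lists. Red and blue points are at least 2-fold higher or lower and grey points lie inside the shaded 2-fold band; the dotted line is the median of all genes (0.18) and the dashed orange line the value at which a gene equals the spike-in controls (0.87), so that the medians of the adrenal regulators (0.16) and of the CLK and SR list (0.39) lie below that line.

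Among protein-coding genes measured on both arrays, the largest increase was that of C9orf152, an uncharacterised open reading frame (448.8-fold, 8.81; chromosome 9, 112961892 to 112961951). Next came CGA, the common alpha subunit of the glycoprotein hormones (68.5-fold, 6.10), PMEPA1 (68.3-fold, 6.09; a second probe gave 4.44), the desert hedgehog gene DHH (5.86), the collagenase MMP1 (5.86), MIA (5.68), NPC1L1 (5.67), FOSB (5.66), the antithrombin gene SERPINC1 (5.60), NR4A2 (5.55), LEFTY1 (5.43), INHBA, which encodes the activin beta A subunit (5.16), HGD (5.08) and EGR1 (5.07). At the other end stood ANKFN1 (329.9-fold lower, −8.37; chromosome 17, 54558048 to 54558107), whose signal was 49442 on the DMSO array and 94.6 on the CX-4945 array. It was followed by APCDD1, an inhibitor of Wnt signalling (−5.48), SULT2A1 (−5.47), TMEM37 (−5.20), the ammonium transporter RHBG (−5.16), B9D1 (−5.05), the glutamate receptor subunit GRIN3A (−4.93), the cannabinoid receptor CNR1 (−4.69), BRINP2 (−4.69), the ephrin EFNA4 (−4.58), HSD17B8 (−4.54), the Wnt antagonist DKK2 (−4.46), NICN1 (−4.42) and DACH2 (−4.42). All of these kept their direction and a 2-fold difference under every alternative in which they were measured. Several sizes rest on a dim signal, however. DMSO signals were 27.8 for C9orf152, 26.9 for MMP1 and 26.6 for MIA, where the lowest signal well above background was 19.4. On the CX-4945 array RHBG had 21.8, TMEM37 21.1 and DKK2 21.2, against a lowest of 16.3. The folds of such genes are uncertain in size. Among non-coding RNAs measured on both arrays the highest were LOC100506548 (5.92), PYCARD-AS1 (5.58) and the probe assigned to the small nucleolar RNA SNORD25 (5.08). Whether that probe read the small RNA itself or a longer transcript over the same stretch was not tested. The lowest non-coding RNAs by their brightest probe were LINC00467 (−3.92), HOXD-AS2 (−3.42) and LOC102723354 (−3.36). Second probes of LINC00467 and LOC102723354 gave −2.965 and −4.029.

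Some genes could only be bounded, because they were well above background on a single array: 1224 on the CX-4945 array, 441 of them protein-coding, and 1732 on the DMSO array, 624 of them protein-coding. A bound sets the bright signal against the higher of the dimmest probe well above background on the other array and the gene's own signal there. It reached 2-fold for 762 of the genes seen on the CX-4945 array only and for 622 of those on the DMSO array only. Which side held more genes thus depended on the bound required. With CX-4945, TAC1, the precursor of substance P, was at least 119.6-fold higher, C15orf59-AS1 at least 118.9-fold, the homeobox gene IRX4 at least 97.3-fold and the metalloproteinase MMP10 at least 92.4-fold. With DMSO, FAM166B was at least 29.6-fold higher, the adrenergic receptor gene ADRA2A at least 26.6-fold, the non-coding MIMT1 at least 22.6-fold and the transcript ENST00000451217 at least 22.04-fold.

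Signalling and stress lists set apart the largest coordinated differences. In the ATF4 and integrated stress response list, 20 of 31 measured members were 2-fold higher and 1 lower, with a median of 1.76 above all 10000 random lists and of 0.89 relative to the spike-ins. TRIB3 (3.45), CHAC1 (3.37) and ATF3 (3.29) led it, its other 2 probes gave 2.96 and 0.94, and VLDLR was lower (−2.00). Immediate early genes, which respond within minutes to growth factors or stress, were 2-fold higher in 19 of 27 cases and lower in 0, with a median of 1.587, again above all random lists, and 0.72 relative to the spike-ins. FOSB (5.66), NR4A2 (5.55) and EGR1 (5.07) stood highest, and FOSL1, EGR4, DUSP2 and ARC were well above background on the CX-4945 array only; with these 4 at their bounds the median was 1.67. NF-kB targets had a median of 1.03 (percentile 99.96), or 0.16 relative to the spike-ins. Of 15 measured members 8 were higher, led by NFKBIZ (2.28), NFKB2 (2.13) and RELB (2.04). The 2 lower were VCAM1 (−2.71) and TRAF1 (−1.22, below 2-fold under normexp). Relative to the spike-ins 3 were higher and 4 lower. Another 13 of the 30 listed NF-kB targets were not above background. Few members of the unfolded protein response list passed 2-fold (2 higher and 1 lower of 26), among them the chaperone gene HSPA5 (2.82) and XBP1 (2.04), and its median of 0.49 (percentile 96.8, and 97.7 among protein-coding genes only, a background chosen after seeing the data) was −0.38 relative to the spike-ins.

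The cAMP and protein kinase A list holds components of the pathway as well as responsive genes, and it shares FOSB and NR4A1 with the immediate early list. Of its 24 measured members, 9 were 2-fold higher, including the growth factor gene AREG (5.04). The 3 lower were ADCY3 (−1.49), PPARGC1A (−1.33, below 2-fold under normexp) and PDE4B (−1.15). The list's median of 0.53 (percentile 97.53) was −0.34 relative to the spike-ins. Angiotensin II and potassium signalling genes, which control aldosterone synthesis, had a median of −0.37 (percentile 2.06) that was negative under every scaling and 0.31 under the stricter filter on dim probes; 6 of 19 were lower, led by the potassium channel KCNJ5 (−3.37), VSNL1 (−2.59) and CAMK1 (−2.20), and CACNA1H (1.30), RGS2 (1.30) and PRKCA (1.17) were higher, but below 2-fold relative to the spike-ins, and PRKCA also under normexp and median centring. Wnt and beta-catenin targets stood lowest of all lists, with a median of −1.22, below all 10000 random lists and negative under every scaling. In that list 11 of 20 members were 2-fold lower, including APCDD1 (−5.48), ISM1 (−4.01) and NKD1 (−3.61), and 4 were higher, including DKK1 (2.12), SFRP1 (1.28) and MYC (1.16); relative to the spike-ins, SFRP1 and MYC were below 2-fold, and MYC also under normexp, median centring and loess. LGR5 was at least 2.86-fold higher with DMSO and CCND1, the cyclin D1 gene, at least 13.0-fold higher with CX-4945, and with the 5 members seen on a single array at their bounds the median was −1.13.

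Proliferation genes were lower in part. G2/M and mitosis genes had a median of −0.46, below all 10000 random lists and negative under every scaling, with 8 of 46 lower, HMMR (−2.63), AURKA (−1.56) and CCNB1 (−1.37) the most, and 0 higher; a second probe of CCNB1 gave 0.09. S phase and DNA replication genes had a median of −0.09 (percentile 2.93, and 9.17 among protein-coding genes only), with 4 of 50 lower, including the primase PRIM1 (−3.10), POLA2 (−2.06) and RRM2 (−1.60), and 2 higher, POLE (1.34) and CDT1 (1.30), both below 2-fold relative to the spike-ins. Of 30 p53 targets, 8 were higher and 1 lower, or 6 and 11 relative to the spike-ins. Their median was 0.30 (percentile 80.5), −0.58 relative to the spike-ins and 0.14 with 1 gene seen on the DMSO array only at its bound. BBC3 (4.20), SESN2 (3.19) and GADD45A (2.98) were the highest and FDXR was lower (−1.16). The other 21 lay inside 2-fold on the main scaling, among them CDKN1A (−0.20), MDM2 (0.54) and BAX (−0.40). SESN2 is also a member of the integrated stress response list. Apoptosis regulators were centred on 0.17 (percentile 56.6; −0.06 after median centring and −0.70 relative to the spike-ins), with BBC3, HRK (2.43) and MCL1 (1.89) among 7 of 29 higher, and CASP6 (−1.28) and CASP9 (−1.12) the 2 lower.

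**Figure D3:**
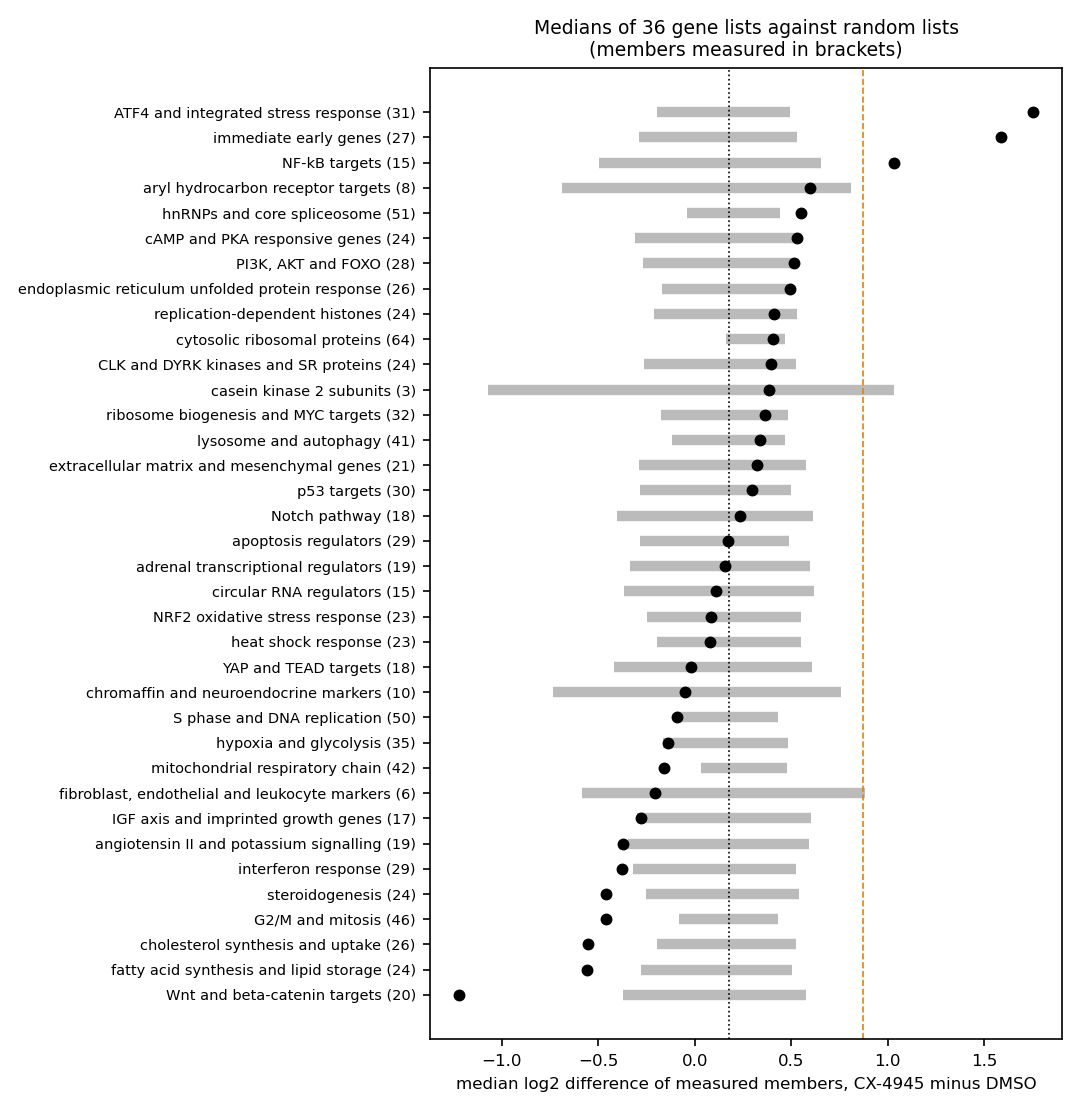
Median log2 difference, CX-4945 minus DMSO (x axis), of the measured members of each of the 36 gene lists (black points; number of members in brackets) against the central 95% of 10000 random lists matched on signal (grey bars). The integrated stress response (1.76), immediate early genes (1.587) and NF-kB targets (1.03) lie to the right of their bars and of the dashed line of the spike-in controls (0.87), and Wnt targets (−1.22) farthest to the left; the dotted line is the median of all genes (0.18).

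Of 19 markers of fibroblasts, endothelium and leukocytes, 6 were measured, and they went both ways: CD14 (4.37) and DCN (2.70) were higher and COL1A1 (−2.53) lower, with a median of −0.21 (percentile 12.1, above 0 under normexp). Chromaffin and neuroendocrine markers had a median of −0.05 (percentile 32.4, above 0 under normexp), with 4 of 10 measured members higher, SCG5 (4.12), SCG2 (3.24), SCG3 (2.24) and ENO2 (1.81, below 2-fold relative to the spike-ins), and 0 lower. The adrenal medullary enzyme gene PNMT was well above background on the CX-4945 array only. With it and 3 members seen on the DMSO array only at their bounds, the median of the chromaffin list was −0.19, and with 1 seen on the DMSO array only that of the other markers was −0.01. The list members named here as seen on a single array were chosen after their values were seen.

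Since CX-4945 acts on splicing kinases, different probes of the same gene were compared. Among 4293 genes with at least 2 probes well above background on both arrays, 1151 (26.8%) had probes whose log2 differences lay at least 1 apart, and 66 had probes at least 2-fold higher and 2-fold lower. C1orf56 gave −4.85 and 0.80 at probes on chromosome 1 (151022984 to 151023043 and 151023792 to 151023851). The centromere protein gene CENPN gave −2.86 at a probe joining separate pieces of chromosome 16 (81053871 to 81056408) and 2.62 farther downstream (81066653 to 81066712). ZNF174 gave −4.36 and 0.89, STAU2 −3.32 and 1.36, RBBP4 −0.79 and 3.21, and SREBF1, the regulator of fatty acid synthesis, −2.32 and 0.32. The paired probes of CENPN, ZNF174 and STAU2 were annotated to different transcripts of the gene. Those of C1orf56, RBBP4 and SREBF1 were annotated to the same transcript. The SREBF1 probes lay close together (transcript positions 4185 and 4300), and the second was much dimmer (mean log2 signal 0.004 against 3.674). Exon and UTR annotation of the probes was not used here, so the differences between probes are not assigned to isoforms or alternative 3' ends. Except for SREBF1, which the lists name, these genes were chosen after their values were seen, from the 12 with the largest gaps.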

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

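Of the explanations weighed here, the test for a brighter DMSO scan and the test for less labelled RNA were chosen only after the result had been seen, and the test for degraded RNA before. The control probes drew attention because the main scaling does not use them. Of 96 ERCC control probes, 1 was well above background on both arrays (signals 28.7 and 22.1), so ERCC transcripts gave no scale. Of 10 E1A spike-in probes, 7 were above background on both arrays, and before scaling they were higher on the CX-4945 array by a mean of 0.207 (range 0.166 to 0.248).

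The 75th percentile over all non-control probes was lower on the CX-4945 array by 0.66, which is 0.87 below the spike-ins, and the median of the genes measured on both arrays lay at −0.69 relative to the spike-ins. A brighter scan of the DMSO array would have lowered the spike-ins on the CX-4945 array as well, and at 0.207 they were higher, so that explanation did not hold. Degraded RNA would have lowered 5' probes against 3' probes of the same gene, and the median difference was 0.009 over 2842 genes (bootstrap 95% interval −0.008 to 0.026). Less labelled RNA would have lowered dim and bright transcripts alike, and the medians of 8 signal bins lay within 0.249 of each other, but a true drop of polyadenylated RNA per total RNA could give the same, so these remain undecided. Spike-in amounts and RNA input were not in the files.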

How the results depend on the processing

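No paired analysis was possible because each condition had 1 array; for the same reason leaving an array out was not possible, and the slide was not run as a block because both arrays lay on 1 slide. The cause of the changes below was not tested, except that thresholds, filters and detection flags change by construction which genes are counted. Median and spike-in centring also shift every value by the same constant.

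Counts of genes at least 2-fold higher and lower, 2599 and 2617, were 721 and 6865 after centring on spike-ins, 6646 and 4543 with no filter on dim probes and 1088 and 1132 with the stricter filter. The higher count was 1542 under normexp. At 1.5-fold they were 5574 and 4171 and at 3-fold 1049 and 1307. With the other scalings, the series value table, outlier spots kept and a mean over the gene's probes both counts stayed within 1.5 times the main ones.

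Medians of the 4 main lists (−0.46 for steroidogenesis, −0.56 for cholesterol, 0.16 for adrenal regulators, 0.39 for CLK, DYRK and SR genes) moved as follows. Centring on spike-ins gave −1.331, −1.427, −0.713 and −0.478 in that order, median centring −0.697, −0.793, −0.079 and 0.156, and loess −0.725, −0.734, 0.010 and 0.223. Normexp gave −0.670 for cholesterol, 0.048 for adrenal regulators and 0.245 for CLK, DYRK and SR genes. Quantile normalization gave −0.667 for steroidogenesis, −0.667 for cholesterol and 0.320 for CLK, DYRK and SR genes, and the value table −0.665 for steroidogenesis and −0.665 for cholesterol. The stricter filter gave −0.325, −0.645 and 0.343 for the first 3 lists, and the mean over probes 0.568 for CLK, DYRK and SR genes. Steroidogenesis and cholesterol were negative throughout, though no scaling tried moved the median of all genes up.

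Centring on spike-ins gave 19 of 36 list medians the other sign. Among lists outside the central 95% of random lists, these were hnRNPs (−0.320), cAMP and protein kinase A genes (−0.340) and PI3K, AKT and FOXO genes (−0.355). The stricter filter turned angiotensin II and potassium signalling (0.306). Over all 36 lists, 0 medians moved beyond the spot SD with outlier spots kept or no filter, and 11 with a mean over probes. Quantile normalization or the value table moved 14, the stricter filter 18, normexp 31, and median centring, loess and centring on spike-ins 36. With no filter the members stayed those of the main setting and dimmer members were not added, so that alternative could not test these medians. Protein-coding genes as the only background, chosen after seeing the data, left steroidogenesis and cholesterol below the central 95% of random lists and the other 2 main lists inside it, though adrenal regulators moved from percentile 47.3 to 75.3.

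Of 215 genes under the naming rule, 52 moved beyond the spot SD under quantile normalization and 57 with the value table. A mean over probes moved 40, normexp 198, and median centring, loess and centring on spike-ins all 215. Of the 176 past 2-fold, 0 changed sign where measured, and under the stricter filter 102 of them were measured. Median and spike-in centring could not turn such a sign, because both shifts were smaller than 1. Genes with probes at least 1.5 apart numbered 596, against 1151 at 1. With the positive-and-significant flag, 3530 genes were detected on the DMSO array only and 3694 on the CX-4945 array only, against 1732 and 1224. Signal over background limited the rest: a gene well above background on 1 array has a bound only.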

Other observations

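Percentiles among protein-coding genes only were chosen after seeing the data, and the other tests in this part before the result was seen. The remaining gene lists are given first, as medians with percentiles among random lists. Fatty acid synthesis and lipid storage genes had a median of −0.56 (percentile 0.14), negative under every scaling, with 9 of 24 lower, including FADS1 (−3.14), SREBF1 (−2.32, a second probe 0.32) and GPAM (−1.95). Interferon response genes had a median of −0.38 (percentile 1.47, 4.84 among protein-coding genes), negative under every scaling, with 10 of 29 lower, including IFI44L (−3.87), IFIT1 (−2.91) and ISG15 (−2.55), and ISG20 higher (1.24; below 2-fold relative to the spike-ins). Respiratory chain genes had a median of −0.16 (percentile 0.02) and hypoxia and glycolysis genes −0.14 (percentile 3.31, 8.69 among protein-coding genes), both negative under every scaling. Of 42 respiratory chain genes 6 were lower, including UQCRC2 (−1.64), and 0 higher, and of 35 hypoxia genes 6 were lower, including SLC16A3 (−2.84), and 6 higher, including NDRG1 (3.23). IGF and imprinted growth genes had a median of −0.28 (percentile 3.13, 10.26 among protein-coding genes), negative under every scaling, with 2 of 17 lower, including PEG3 (−3.46, another probe −0.36), and 3 higher, including GRB10 (2.99).

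PI3K, AKT and FOXO genes had a median of 0.52 (percentile 97.8; −0.36 relative to the spike-ins), with 7 of 28 higher, including TRIB1 (2.66) and CCNG2 (2.34), and 2 lower. Relative to the spike-ins the sign also turned for aryl hydrocarbon receptor targets (0.60, percentile 90.4; TIPARP 1.24), replication-dependent histones (0.41, percentile 90.5; HIST2H2BE 1.69, another probe 0.35, read among close paralogs), cytosolic ribosomal proteins (0.41, percentile 87.7, 98.5 among protein-coding genes; RPL22 1.96), ribosome biogenesis and MYC targets (0.36, percentile 88.0; NOP2 1.46, UTP20 −2.10), lysosome and autophagy genes (0.34, percentile 86.3; UVRAG 2.504) and extracellular matrix genes (0.32, percentile 74.3; SNAI1 2.65, SNAI2 −2.47). TIPARP, HIST2H2BE and NOP2 were below 2-fold relative to the spike-ins.

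Notch pathway genes had a median of 0.23 (percentile 61.1; below 0 after median centring and relative to the spike-ins; 0.41 with 1 gene seen on the CX-4945 array only at its bound), with HEY1 (2.09) higher and HEY2 (−2.93) lower. Heat shock genes stood at 0.08 (percentile 25.7; below 0 after median centring, loess and relative to the spike-ins; HSPB8 −2.46), and NRF2 targets at 0.08 (percentile 32.5; below 0 under normexp, quantile normalization, median centring, loess, the value table and relative to the spike-ins; PIR −3.71, SLC7A11 1.29, below 2-fold relative to the spike-ins). YAP and TEAD targets stood at −0.02 (percentile 27.6; above 0 under normexp; GADD45B 2.13, FJX1 −2.02).

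A hypothesis was that altered splicing lowers probes that join separate genomic pieces. A probe counted as joining when its genomic span was longer than the probe. That took in a span of 61 bases for a probe of 60, as for HSD3B1. Probes with only part of their length placed, as in ENSA, counted as non-joining, so the groups are not cleanly separated. Over 581 genes, joining minus other probes of the same gene had a median of −0.064 (bootstrap 95% interval −0.101 to −0.037), the direction that the hypothesis predicted. Gaps of at least 1 occurred in 14.8% of these pairs and between non-joining probes in 20.9% of 2842 genes. The share for non-joining probes was 9.64% under 1 kb apart and 23.9% over 1 kb apart, and spacing was not matched to the joining pairs. Over all non-joining probes, negative gaps of that size also outnumbered positive ones (12.5% against 8.37%). Distance from the 3' end did not account for the negative median, since it was −0.097 where the joining probe lay on the 3' side. Neither did dim probes, since the median was −0.089 with signals matched, though over 96 genes and with an interval that came close to 0 (−0.170 to −0.005). The difference is small and rests on 2 libraries, so it stays a hypothesis.

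Another hypothesis was that longer genes were lower. Spearman's rho of gene length with the log2 difference was −0.070 across 12475 protein-coding genes, which are not independent replicates, and lay between the values fixed beforehand for either outcome, so the test could not tell. In the longest of 5 equal groups of genes (median 152.9 kb) 10.4% were 2-fold higher and 19.6% lower, and in the shortest (4.61 kb) 15.1% and 14.3%.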
